A study of Homo sapiens with 6 samples.

How the data were processed

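RNA was measured by sequencing in HK-2 cells, an immortalised human proximal tubule epithelial line. Cells had received either an empty adenovirus (Ad-null, 3 libraries) or an adenovirus carrying RORγ (Ad-RORγ, 3 libraries). The deposited values were raw counts per gene, whole numbers with totals that differed between libraries, in a single table of 35041 gene names by 6 libraries. The reads were placed on the human genome build hg38 (GRCh38.p13), per the submitters' processing notes. The aligner, the counting tool, its annotation and its use of strand are not given in the sources used here. The labels' protocols describe full-length cDNA and long-read template preparation, and do not say how the 39006635 to 58170329 counts per library were obtained from it, so the read type behind the counts is open. Where near-identical genes share reads, or genes overlap on opposite strands, the split of counts between them is uncertain.

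The table named genes by symbol only. Of these, 11854 were LOC names and 27 had been turned into calendar dates, as spreadsheet programs do to symbols such as those of the septins; 4 of the 27 shared a name with another. The date-like names held between 0.163% and 0.229% of the counts of a library and stayed in the library sizes. Mitochondrially encoded genes (a list of 13) were not analysed here. Coordinates, transcript lengths and GC content came from GENCODE release 29 (GRCh38); 22781 names matched directly, 142 through an older or newer symbol, and 12118 did not match. The longest transcript of a gene, coding where possible, gave its length and GC content.

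Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16122 genes. Libraries were scaled by TMM factors. The quasi-likelihood test (glmQLFit with the robust option, then glmQLFTest) compared Ad-RORγ with Ad-null with no other term, two-sided and with 4 residual degrees of freedom per gene, and p-values were adjusted by the method of Benjamini and Hochberg. A gene with an adjusted p under 0.05 was called changed. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. All adjusted p-values for genes in the text are from this test unless another is named. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Levels are CPM (counts divided by library size and TMM factor, on a per-million scale) computed here from the deposited counts with the TMM factors, given as mean ± SD with n = 3. Where every library of a group was at 0, the fold change was bounded with 3 counts over the group's 3 libraries. Intervals and floors cover counting error only where they come from counts alone.

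Before the data were examined, 36 gene lists were fixed. The 33 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, adjusted over the 33 lists. Camera called 4 of the 33. With the correlation estimated per list it called 0 (2 at an unadjusted p under 0.05), while rank-based camera called 4 and fry, which does not compare a list with other genes, 18. For each list the number of changed members is given over all genes and adjusted over the list alone. These numbers are to be read against the 5411 of 16122 tested genes called, 2819 higher and 2592 lower. A list with a like share of called members does not stand out. Genes named in the text followed a rule fixed at the same time: the 10 highest and 10 lowest fold changes among called genes with a mean of at least 1 CPM and no overlap between the groups, the 5 smallest adjusted p-values in each direction, up to 4 called members of each list with the smallest adjusted p, and 23 genes fixed by name. Genes named outside this rule are said to be so. Some genes that the rule names, and 1 of the lists, are not reported here.

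The fit was checked on simulated counts drawn from the means and library sizes of the 16122 genes, with 200 genes changed. The test recovered 22.4% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 95.5% of those changed 4-fold, and 4.44% of its calls were unchanged genes. Alternatives chosen at the same time were other scalings, DESeq2 1.42.0, limma-voom, looser and stricter filters, a fit without the robust option, the replicate number as a block, each library left out in turn, rank-based camera, a prior count of 0.5 in camera, and glmTreat against a 1.2-fold change. Chosen after seeing the data were an offset that removes each library's smooth trend on GC content (lowess, span 0.3), the same for GC content and transcript length, and leaving out both libraries numbered 3. On simulated counts that also carried the libraries' GC trends, the GC offset recovered 79.1% of genes changed 2-fold, and 12.0% of its calls were unchanged genes. The main test was not run on those counts, so its shares above cannot be compared with these. Its larger counts of calls in the data may therefore hold more unchanged genes than the threshold implies. On counts with the GC trends and no changed genes, the main test and the GC offset each called 0 genes. Figures were drawn with matplotlib 3.10.9.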

Results

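Transcript counts were compared in HK-2 cells, an immortalised line of human proximal tubule epithelium, after infection with an adenovirus carrying RORγ or with an empty adenovirus. RORγ is a nuclear receptor, and the series title places it among energy-sensing molecules that act on cholesterol metabolism and immune signalling in the diabetic and ageing kidney. The question put to these cells was how their transcripts change when RORγ is overexpressed. Each group held 3 libraries. The Ad-null libraries held 39006635, 47569059 and 39713040 counts (replicates 1 to 3) and the Ad-RORγ libraries 49101449, 45409664 and 58170329.

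Many genes differed between the groups. Of 16122 genes tested, 5411 passed the threshold, 2819 higher and 2592 lower in Ad-RORγ. At a change of at least 2-fold the counts were 830 higher and 598 lower. Once the trends on GC content were removed, they were 511 and 456 among the 14489 genes that could be tested. With upper-quartile factors the balance of all calls turned, to 2348 higher and 3077 lower, and with total counts alone it was 2717 and 2743. Among the genes that rose most, several came from very low levels. IVL, which encodes the cornified envelope protein involucrin, had 0 counts in all Ad-null libraries and 149, 134 and 139 counts in Ad-RORγ replicates 1, 2 and 3, at least 117-fold higher against a floor of 3 counts over the Ad-null group. TRIM67 rose 119-fold (0.834 ± 0.187 to 99.8 ± 9.95 CPM, SD, n = 3) and NCCRP1 59.3-fold, while SCEL, another cornified envelope gene, rose 50.3-fold. The placental alkaline phosphatase genes ALPP and ALPPL2 rose 55.9-fold and 58.6-fold, but they are near-identical neighbours on chromosome 2 whose reads may be shared. RAET1E, a ligand of the immune receptor NKG2D, rose 36.4-fold, from 1.49 ± 0.165 to 54.1 ± 2.58 CPM. The genes that fell most were TNFRSF6B, a decoy receptor for Fas ligand, with a log2 fold change of -3.02 ± 0.29 (SE), and MGAT3, ANO2, SLN and GPSM3, from -2.90 to -2.70. ALDH1A3, a retinaldehyde dehydrogenase, fell from 185 ± 10.9 to 42.1 ± 2.04 CPM (edgeR's quasi-likelihood test, adjusted p = 2.1e-05).

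**Figure D1:**
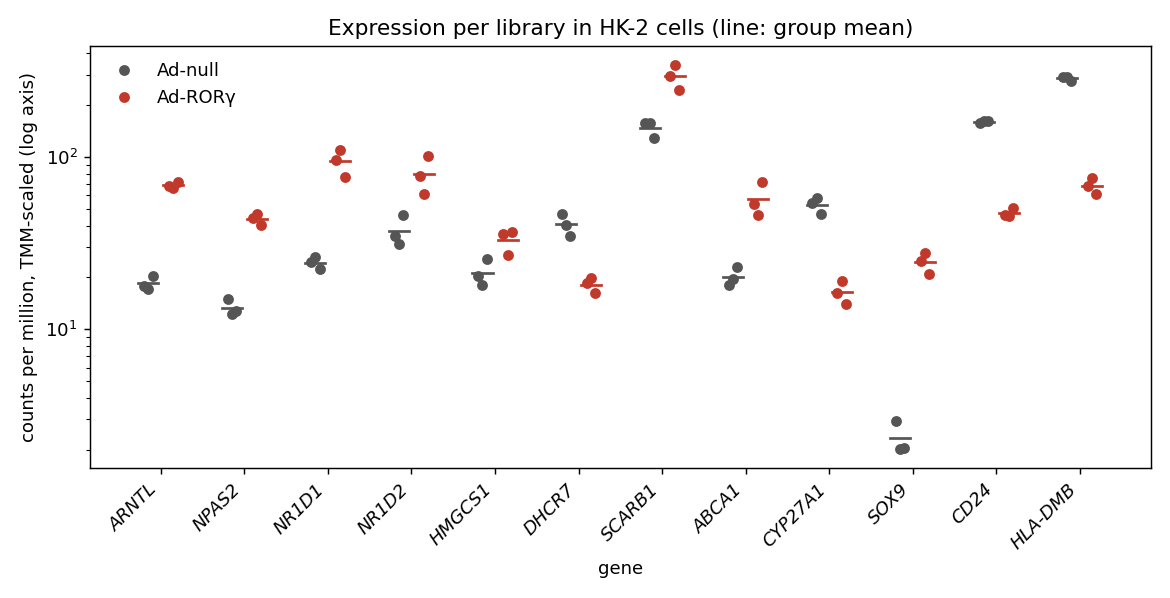
Expression of 12 named genes in each library, in TMM-scaled CPM on a log axis; points are libraries, horizontal lines are group means, grey is Ad-null and red is Ad-RORγ (n = 3 each). ARNTL has means of 18.5 and 68.5 CPM in Ad-null and Ad-RORγ, and HLA-DMB of 286 and 68.4 CPM.

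The number of genes called depended on the libraries. It was 2242 without Ad-null replicate 1, 2595 without Ad-null replicate 2 and 2656 without Ad-RORγ replicate 1. It was 4251, 6277 and 6729 without Ad-RORγ replicate 3, Ad-null replicate 3 and Ad-RORγ replicate 2. The first principal component, which separated the groups, held 65.6% of the variance. Fold changes also moved with base composition: across 14489 genes the Spearman correlation of log2 fold change with transcript GC content was -0.49, and over 5 equal groups of genes by GC content the medians ran from 0.45 at the lowest GC content to -0.28 at the highest. Genes are not independent replicates, so this correlation has no p-value here. Per library the correlation with GC content was 0.55, 0.61 and -0.12 in Ad-null replicates 1 to 3 and -0.45, 0.19 and -0.67 in Ad-RORγ replicates 1 to 3, a group difference with p = 0.20 in a two-sided exact permutation test whose smallest possible p is 0.10. Leaving out both libraries numbered 3, the lowest of each group in this trend, gave a correlation of -0.47 and 7393 genes called. With the GC trends removed, 89.3% of the called genes that could be tested kept their direction and their call.

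**Figure D2:**
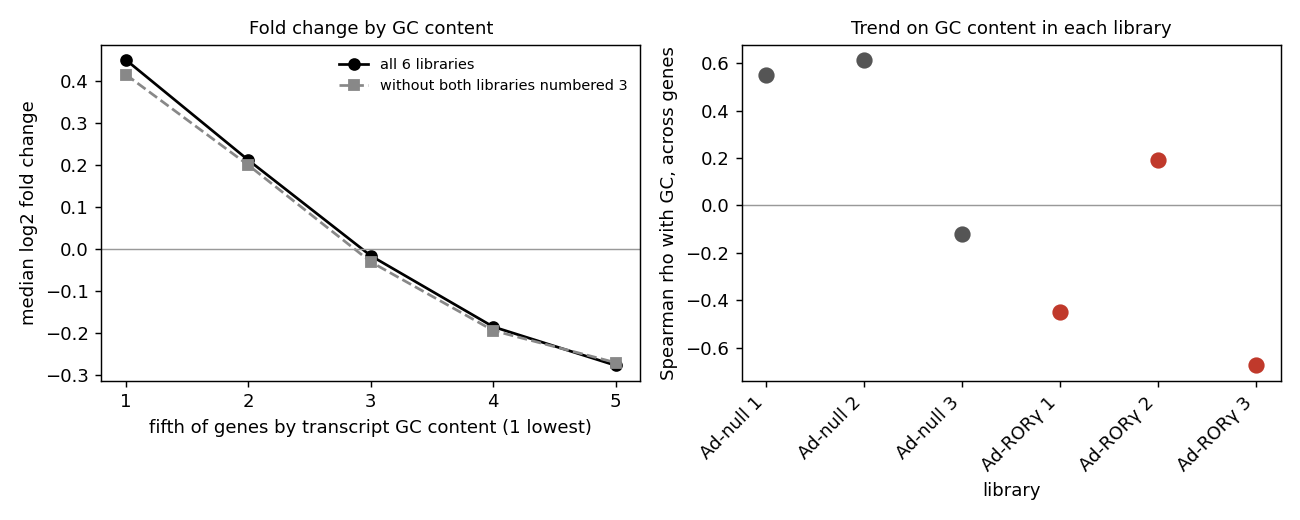
Left, median log2 fold change of genes in 5 equal groups by transcript GC content (1 lowest), for all 6 libraries and without both libraries numbered 3; right, Spearman correlation across genes of each library's deviation from the gene mean with GC content, grey for Ad-null and red for Ad-RORγ. The medians run from 0.45 to -0.28, and the libraries from 0.61 to -0.67.

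Genes of cholesterol metabolism, the subject of the series title, changed in both directions. Among 21 tested genes of cholesterol biosynthesis, 3 rose, 6 fell and the rest were not called; adjusted over the list alone the numbers were 5 and 6. HMGCS1 and SQLE, enzymes of the pathway, rose by 0.64 ± 0.17 and 0.35 ± 0.10 (SE) on the log2 scale (adjusted p = 0.024 and 0.029). DHCR7, an enzyme of the last steps, fell from 40.6 ± 5.94 to 18.2 ± 1.85 CPM, a log2 fold change of -1.16 ± 0.14 (adjusted p = 0.0011), and MVK fell by 0.59 on the log2 scale. The list as a whole was not called (camera, adjusted p = 0.56). Fry for changes in either direction gave an adjusted p of 0.0086. That does not set the list apart, since fry's adjusted p for either direction was under 0.05 for every tested list (highest 0.017, heat shock). With the GC trends removed the values of HMGCS1 and MVK were 0.26 and -0.36, and both kept their calls. The calls of HMGCS1, SQLE and MVK were lost without Ad-null replicate 1 (adjusted p = 0.097, 0.12 and 0.085), without Ad-null replicate 2 (0.090, 0.12 and 0.067) and without Ad-RORγ replicate 1 (0.086, 0.12 and 0.063), and that of SQLE also without Ad-RORγ replicate 3 (0.051) and with upper-quartile factors (0.057). Over all alternatives the adjusted p ranged from 1.8e-13 to 0.097 for HMGCS1, from 2.7e-06 to 0.20 for SQLE and from 3.3e-12 to 0.085 for MVK.

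Of 18 genes of SREBP control and sterol uptake, 4 rose and 4 fell (6 and 4 adjusted over the list alone). SCARB1, the HDL receptor, rose from 148 to 294 CPM, by 0.99 ± 0.14 on the log2 scale (adjusted p = 0.0023), and NPC2, which carries cholesterol out of lysosomes, had a log2 fold change of -0.65 ± 0.09. INSIG1 was not called (-0.22 ± 0.10, adjusted p = 0.12) but was with the GC trends removed (0.011; range over all alternatives 0.0082 to 0.61). SREBF2 was not called (0.16 ± 0.13, adjusted p = 0.36) but was with the GC trends removed (0.37, adjusted p = 0.00043; range over all alternatives 0.00043 to 0.76). Of 13 tested genes of cholesterol efflux and oxysterols, 4 rose and 4 fell, the same numbers adjusted over the list alone. ABCA1, the main exporter of cellular cholesterol, rose 2.82-fold (20.2 ± 2.42 to 57.1 ± 13.4 CPM, adjusted p = 0.0010) and NCEH1 1.78-fold, while CYP27A1, the sterol 27-hydroxylase, and NR1H3, which encodes LXRα, had log2 fold changes of -1.68 ± 0.15 and -0.96 ± 0.14. ABCG1 had 0 counts in every library. Neither list was called by camera (adjusted p = 0.81 and 0.78).

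Of 19 tested genes of the circadian clock, 9 rose, 1 fell and 9 were not called, over all genes and adjusted over the list alone, with a median log2 fold change of 0.30 over all 19 (0.26 with the GC trends removed). ARNTL, which encodes BMAL1, rose 3.70-fold (18.5 ± 1.71 to 68.5 ± 2.65 CPM, adjusted p = 5.0e-05), NR1D1, which encodes the repressor REV-ERBα, 3.87-fold, NPAS2 3.27-fold and NR1D2 2.15-fold. The member that fell was CIART (-0.39), named here after its value was seen, and CRY1 was not called (0.21 ± 0.10, adjusted p = 0.14) but was with the GC and length trends removed (0.048; range over all alternatives 0.0022 to 0.63). The list was called by camera (adjusted p = 0.021, and adjusted p = 0.52 with an estimated correlation), and over all alternatives its adjusted p ranged from 0.0017 with the GC trends removed to 0.52. The list of RORγ targets described in liver and other tissues, which holds ARNTL, NPAS2 and NR1D1 too, had 6 of 12 tested members higher and 2 lower (7 and 3 adjusted over the list alone), with PPARG, the adipogenic nuclear receptor, up 1.52-fold, and was not called by camera (adjusted p = 0.094), though it was with at least 1 CPM required in 3 libraries (0.025; range over all alternatives 0.025 to 0.52, the highest with an estimated correlation). With the GC trends removed its median fell from 0.58 to 0.30.

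The Th17 list, of genes tied to the interleukin-17 T helper lineage that RORγ is known for, had 6 of 8 tested members higher and 0 lower, also when adjusted over the list alone. The count of lower members was also 0 at an unadjusted p under 0.05 in edgeR's quasi-likelihood test, and 0 by DESeq2 and limma-voom. Camera called the list (adjusted p = 0.021, and adjusted p = 0.52 with an estimated correlation), and its median was 0.92, or 0.59 with the GC trends removed. Of the members that rose, RUNX1 and AHR are transcription factors, IL1R1 is the interleukin-1 receptor and CCL20 a chemokine, and HIF1A and MAF, named after their values were seen, are transcription factors. CCL20 rose 5.89-fold, from 0.908 ± 0.336 to 5.35 ± 0.658 CPM, and RUNX1 2.04-fold. The call of AHR was lost with the GC trends removed (log2 fold change from 0.65 ± 0.13 to 0.20, adjusted p = 0.075) and without Ad-null replicate 1 (adjusted p = 0.055; range over all alternatives 5.6e-17 to 0.31). IL17A, IL17F and IL21, named after their values were seen, had 0 counts in all libraries.

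Immune genes fell more often than they rose in several groups. Of 24 tested genes of antigen presentation, 12 fell and 1 rose (15 and 2 adjusted over the list alone), with a median log2 fold change of -0.36. HLA-DMB, a chaperone of class II peptide loading, fell from 286 ± 9.59 to 68.4 ± 6.97 CPM (log2 fold change -2.07 ± 0.10, adjusted p = 3.2e-05), and HLA-DMA and HLA-F fell by 1.34 and 0.89 on the log2 scale. CD274, which encodes the checkpoint ligand PD-L1, was the member that rose, 2.96-fold. HLA genes are closely related and polymorphic, so the split of reads among them is uncertain. Camera called the list (adjusted p = 0.021, and adjusted p = 0.90 with an estimated correlation), but not without Ad-RORγ replicate 3 (0.053) or with the GC trends removed (0.054), where the median was -0.21; over all alternatives the adjusted p ranged from 0.011 to 0.90. Of 40 tested interferon-stimulated genes, 16 fell and 4 rose (16 and 5 adjusted over the list alone): RSAD2, IFITM1 and OAS1 had log2 fold changes of -1.55, -1.16 and -1.13, and GBP2 rose 2.35-fold. That list was not called by camera (adjusted p = 0.099), yet it was without Ad-null replicate 2 (0.048), without Ad-RORγ replicate 3 (0.034) and with the GC trends removed (0.049; range over all alternatives 0.034 to 0.52). With an estimated correlation its adjusted p was 0.52, and 0.64 with the GC trends removed too.

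Of 28 tested genes of nucleic acid sensing, 8 fell and 4 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.31). TMEM173, which encodes STING, and PYCARD, the inflammasome adaptor, had log2 fold changes of -1.63 ± 0.17 and -1.61 ± 0.18, and IKBKE and GSDMD fell by 1.26 and 0.84 on the log2 scale. Of 33 tested genes of NF-kB and inflammatory cytokines, 10 rose and 10 fell (10 and 12 adjusted over the list alone). The subunit genes NFKB1 and RELB had log2 fold changes of -0.94 ± 0.08 and -1.26 ± 0.13, and the chemokine CXCL5 fell from 145 to 73.9 CPM, while the chemokine CCL2 rose 1.95-fold. IL6 was not called (-0.39 ± 0.13, adjusted p = 0.058), but passed the threshold without Ad-RORγ replicate 2 (0.045), without both libraries numbered 3 (0.016), with upper-quartile factors (0.034) and with the GC trends removed (0.0065; range over all alternatives 0.00013 to 0.21). CXCL8 passed the threshold (0.56 ± 0.15, adjusted p = 0.025), but with the GC trends removed its value was -0.053 (adjusted p = 0.69), and the call was also lost without Ad-null replicate 1 (0.098), Ad-null replicate 2 (0.089) or Ad-RORγ replicate 1 (0.066; range over all alternatives 1.7e-14 to 0.87). The median of the list was 0.10 while its mean (-0.019) and camera's direction were negative (adjusted p = 0.81). That median was 0.012 without Ad-null replicate 3, 0.0095 without Ad-RORγ replicate 2 and -0.050 with the GC trends removed. Of 29 tested genes of complement and coagulation, 4 rose and 6 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.81, direction down): the extracellular chaperone CLU rose 5.66-fold and the plasminogen activator PLAT 3.24-fold, and C3 fell by 0.85 on the log2 scale. The median of that list was 0.030, but it was negative without any 1 library other than Ad-null replicate 2 (-0.112 to 0.0037 over the 6 omissions), without both libraries numbered 3 (-0.029) and with the GC trends removed (-0.22).

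**Figure D3:**
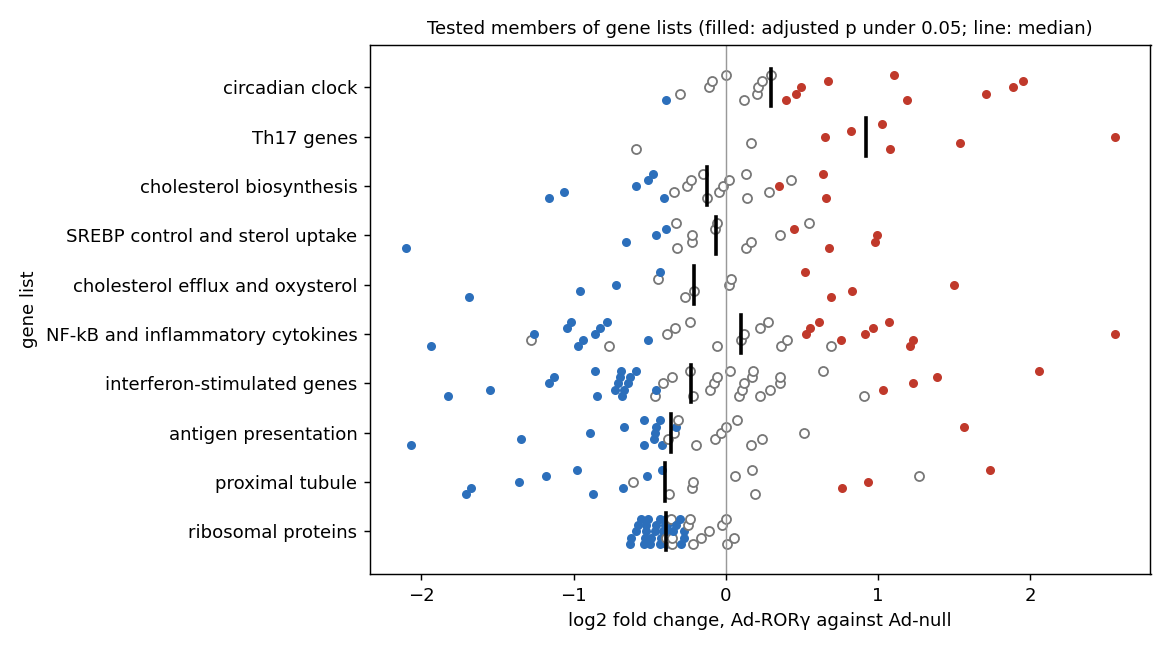
Log2 fold change of every tested member of 10 gene lists, red for called higher, blue for called lower and open for not called; vertical black lines are list medians. Ribosomal protein genes lie close together around a median of -0.39, whereas the cholesterol and cytokine lists spread to both sides of 0.

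Ribosomal protein genes were lower by a small amount. Of 42 tested, 29 fell and 0 rose (32 and 0 adjusted over the list alone), with a median log2 fold change of -0.39; 0 were higher also at an unadjusted p under 0.05 in edgeR's quasi-likelihood test, and 0 by DESeq2 and limma-voom. RPS18 fell from 1844 ± 60.1 to 1281 ± 117 CPM (log2 fold change -0.52 ± 0.10, adjusted p = 0.0058), and RPS14, RPL32 and RPL19 fell by 0.56, 0.54 and 0.46 on the log2 scale. Camera called the list (adjusted p = 2.9e-07, and adjusted p = 0.52 with an estimated correlation). The call of RPL19 was lost with the GC and length trends removed (adjusted p = 0.10; range over all alternatives 7.3e-10 to 0.10). The median was -0.30 with the GC trends removed, -0.21 with the GC and length trends removed, and -0.35 without both libraries numbered 3. Many of these genes have processed pseudogenes that may share reads.

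Genes of the kidney tubule changed in both directions. Of 20 tested proximal tubule genes, 9 fell and 3 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.14); PAX2 and AMN fell by 1.67 and 1.36 on the log2 scale, and the glucose transporter gene SLC2A2 rose 3.33-fold from 0.534 CPM. Of 21 tested genes of tubular injury, 6 rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.98, direction up). Their median was -0.031. It was 0.028 without both libraries numbered 3, -0.18 with the GC trends removed and -0.10 to -0.0016 with a library left out. SOX9, a factor of tubule repair, rose 10.5-fold (2.35 ± 0.526 to 24.5 ± 3.39 CPM), CD24 fell from 160 ± 2.87 to 47.4 ± 2.91 CPM, and KRT19 fell by 1.58 on the log2 scale. HAVCR1, which encodes the injury marker KIM-1, was not called (-0.12 ± 0.12, adjusted p = 0.44). LCN2, which encodes NGAL, had a log2 fold change of -0.55 ± 0.15 (adjusted p = 0.024), a call lost without Ad-null replicate 1 (0.093), Ad-null replicate 2 (0.089) or Ad-RORγ replicate 1 (0.063; range over all alternatives 1.2e-08 to 0.093). Of 35 tested genes of extracellular matrix and fibrosis, 9 rose and 9 fell (9 and 12 adjusted over the list alone; camera adjusted p = 0.78, direction down). Its median was 0.011, and turned sign with RLE size factors, the GC trends removed, both libraries numbered 3 left out and 5 of the 6 omissions of a library, all but Ad-RORγ replicate 1 (-0.11 to 0.031). The crosslinking enzyme gene LOX rose 4.73-fold and MMP9 3.68-fold, whereas THBS1 and CTGF had log2 fold changes of -1.36 ± 0.10 and -1.41 ± 0.11, and FN1, which encodes fibronectin, fell from 5237 to 3033 CPM. Of 18 tested genes of epithelial-mesenchymal state, 7 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.25), among them S100A4, up 7.05-fold, and CLDN2, a claudin of the leaky proximal tubule, with a log2 fold change of -2.33 ± 0.20.

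Genes of cell cycle arrest and of proliferation were both among those that rose. Of 23 tested senescence genes, 8 rose and 6 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.78). The cyclin-dependent kinase inhibitor genes CDKN2B, CDKN1A and CDKN1B rose 2.71-fold, 2.41-fold and 2.07-fold. Of 39 tested cell cycle genes, 14 rose and 8 fell (16 and 11 adjusted over the list alone; camera adjusted p = 0.78), with CCNA2, KIF20A and AURKA up 1.98-fold, 1.64-fold and 1.60-fold and MCM3 lower by a log2 fold change of -0.63 ± 0.08.

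Other metabolic and stress lists held called genes in both directions, as did the tested genes at large (5411 of 16122 called). In the main fit camera called none of them. Among 19 tested genes of fatty acid synthesis, 6 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.78), with SCD, the stearoyl-CoA desaturase, up 1.69-fold. Among 21 of fatty acid oxidation, 6 rose and 1 fell (also over the list alone; adjusted p = 0.78), with ETFDH up 2.65-fold. PPARA and PPARGC1A were not called, at 0.0025 ± 0.093 and 0.025 ± 0.21, and the sign of each differed among scalings: both were negative with upper-quartile factors (-0.061 and -0.039), and PPARA also with RLE size factors (-0.0065). PPARA was called lower with the GC and length trends removed (-0.16, adjusted p = 0.024; range over all alternatives 0.024 to 0.998). With the GC trends removed, PPARGC1A was at -0.35 (adjusted p = 0.0091; range over all alternatives 0.0023 to 0.97). Of 38 nuclear-encoded respiratory chain genes, 4 rose and 8 fell (4 and 7 adjusted over the list alone; adjusted p = 0.25). Of 26 glycolysis genes, 4 rose and 3 fell (4 and 2 over the list alone; adjusted p = 0.89, direction down against a median of 0.031, which was -0.051 without Ad-null replicate 3 and -0.072 without Ad-RORγ replicate 2), with SLC2A3 at -0.87 ± 0.10. Of 24 hypoxia response genes, 6 rose and 2 fell (8 and 2 over the list alone; adjusted p = 0.44), with VEGFA up 1.88-fold. The energy sensing list had 6 of 30 members higher and 4 lower (also over the list alone; adjusted p = 0.89), with FOXO3 up 1.97-fold and SIRT3 at -0.94 ± 0.14. The nuclear receptor and coregulator list had 11 of 30 higher and 2 lower (also over the list alone; adjusted p = 0.44), the latter being NR1H3 and NR3C2, the mineralocorticoid receptor gene (-0.96 ± 0.15).

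Of 29 immediate early genes, 6 rose and 9 fell (6 and 11 over the list alone; camera adjusted p = 0.43), with EGR1 falling from 79.6 ± 1.07 to 20.8 ± 4.37 CPM and DUSP5 rising 2.31-fold. Of 19 heat shock genes, 4 rose and 1 fell (3 and 0 over the list alone; adjusted p = 0.26), with DNAJB4 up 2.75-fold, or 1.77-fold with the GC trends removed. Camera called the heat shock list with the GC trends removed (adjusted p = 0.041, and adjusted p = 0.56 there with an estimated correlation). The range over the alternatives that change 1 setting was 0.0095 to 0.52, the highest with an estimated correlation. Of 30 genes of the unfolded protein response, 6 rose and 6 fell (also over the list alone; adjusted p = 0.83, direction down with a median of -0.062 and a mean of 0.045), with DDIT4 up 1.60-fold and SLC3A2 at -0.70 ± 0.13. Of 26 NRF2 antioxidant genes, 4 rose and 4 fell (4 and 3 over the list alone; adjusted p = 0.89, direction down), with SLC7A11 and GCLM up 3.20-fold and 2.47-fold. With the GC and length trends removed the log2 fold change of SLC7A11 went from 1.68 to 1.01. The median of the NRF2 list was 0.00080, and turned sign with RLE size factors, the GC trends removed and 5 of the 6 omissions of a library, all but Ad-RORγ replicate 3 (-0.075 to 0.0098).

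Many markers of other cell types were not tested because of low counts. Of fibroblast markers 5 were tested and 1 rose, S100A4, which is also in the epithelial-mesenchymal list (1 also over the list alone; camera adjusted p = 0.89, direction up against a median of -0.33, which was 0.042 without Ad-RORγ replicate 2). Of endothelial markers 3 were tested and 1 rose, also over the list alone: TEK, to 1.12 ± 0.0892 CPM. Of leukocyte markers 5 were tested, of which CSF1R rose to 1.11 ± 0.0634 CPM and CD68 and CD14 had log2 fold changes of -1.34 and -0.97 (1 and 3 over the list alone; adjusted p = 0.40 for the list). The call of CD14 was lost without Ad-null replicate 1 (0.067), Ad-null replicate 2 (0.062) or Ad-RORγ replicate 1 (0.0501; range over all alternatives 0.00096 to 0.067). The pan-leukocyte gene PTPRC, named after its value was seen, had 0 counts in all libraries. Of podocyte markers 4 were tested and 2 fell, also over the list alone, SYNPO and PODXL, with log2 fold changes of -0.61 ± 0.12 and -0.79 ± 0.16. Of markers of the distal nephron, another part of the tubule, 5 were tested, 3 rose and 1 fell (3 and 2 adjusted over the list alone; adjusted p = 0.56): SCNN1A, a subunit of the epithelial sodium channel, rose 5.26-fold to 144 ± 16.9 CPM, AQP3 rose 7.80-fold, and CDH16 had a log2 fold change of -1.54 ± 0.17.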

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

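The offsets for GC content and length and the fit without both libraries numbered 3 were chosen after seeing the data. Other scalings, DESeq2, limma-voom, other filters and a fit without the robust option gave between 5059 and 5726 genes. Tested against a 1.2-fold change, glmTreat called 2900 (1524 higher, 1376 lower), as a stricter test must. Leaving out 1 library in turn gave 2242 (without Ad-null replicate 1) to 6729 (without Ad-RORγ replicate 2), of which 1128 to 3503 higher and 1114 to 3226 lower; fewer samples leave less power, and why some omissions raised the count was not tested. At least 2-fold higher were 511 genes with the GC offset and 507 with the GC and length offset, against 830; the offsets tested 14489 of 16122 genes, and the cause of the lower count was not tested. Higher and lower calls were 2348 and 3077 with upper-quartile factors and 2717 and 2743 with total counts alone.

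The replicate block gave 10116 genes (5391 higher, 4725 lower). The labels only share numbers. Deviations of same-numbered libraries correlated at 0.0586, 0.42 and 0.46. Every Ad-RORγ library correlated best with the Ad-null library of its own number, and so did Ad-null replicates 2 and 3 with theirs. Ad-null replicate 1 correlated best with Ad-RORγ replicate 2. Deviations from the group mean also followed GC content. Their Spearman correlations with it were 0.46, 0.62 and -0.74 in Ad-null replicates 1 to 3. In Ad-RORγ replicates 1 to 3 they were 0.10, 0.75 and -0.74. Pairing and a shared GC trend thus cannot be told apart here. The numbers are at most a hint of pairing from the data, not used in the main fit, and not a design.

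With an estimated correlation camera called 0 lists (2 at an unadjusted p under 0.05; fry called 18): adjusted p = 0.52 for ribosomal proteins, circadian clock and Th17 genes and 0.90 for antigen presentation, whose adjusted p was 0.054 with the GC offset, 0.13 with the GC and length offset and 0.011 to 0.053 with a library left out. Interferon-stimulated genes reached 0.049, 0.036 and 0.034 to 0.24 in the same settings. The causes were not tested.

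Values near 0 changed sign, and the cause was not tested. PPARA was -0.0065 with RLE size factors, -0.061 with upper-quartile factors, -0.0057 with DESeq2, -0.0012 with at least 1 CPM in 3 libraries, -0.028 with the GC offset, -0.16 with the GC and length offset, where it was called (adjusted p = 0.024), -0.021 without both libraries numbered 3 and -0.034 to 0.024 with a library left out. PPARGC1A was -0.039 with upper-quartile factors, -0.35 and -0.42 with the offsets, -0.041 without both libraries numbered 3 and -0.19 to 0.19 with a library left out. CXCL8 was not near 0 in the main fit, where it was called higher, but was -0.053 with the GC offset, and the cause was not tested.

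Camera's direction turned for lists not called in any of these settings, with these adjusted p-values. Ranges are over all 6 omissions of a library, whether or not the direction turned, followed by the omissions that turned it. Tubular injury: 0.97 by ranks, 0.99 with at least 1 CPM, 0.81 with the replicate block, 0.85 and 0.99 with the offsets, 0.90 without both libraries numbered 3, 0.92 to 0.997 with a library left out (turned without Ad-null replicate 2 and Ad-RORγ replicate 3). NRF2 antioxidant: 0.85, 0.61, 0.76 and 0.65 to 0.997 (offsets, number 3, left out; turned without Ad-null replicates 1 and 2 and Ad-RORγ replicate 3). Glycolysis: 0.45, 0.43 and 0.77 to 0.98 (Ad-null replicate 2, Ad-RORγ replicate 3). Immediate early genes: 0.85 and 0.71 with the offsets. Extracellular matrix: 0.85 with the GC offset. Unfolded protein response: 0.97 with the GC and length offset and 0.79 to 0.97 (Ad-RORγ replicate 3). Fibroblast markers: 0.97 by ranks, 0.80 with the block, 0.90 without number 3, 0.82 to 0.997 (Ad-null replicate 3). Senescence 0.70 to 0.99 and energy sensing 0.71 to 0.997 with a library left out (both turned only without Ad-RORγ replicate 2, at 0.99 and 0.89).

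Depth limits the low genes: 1 count was worth 0.017 to 0.026 CPM. The simulated test found 22.4% of 1.5-fold changes, but among genes of all levels, so that share does not measure depth. Only 200 genes were changed there, against 5411 called in the data, so recovery in the data may differ.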

Other observations

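The clock tests over all 19 members, by their median and by camera, and by the count of members kept, and the ribosomal test by the joint GC and length offset, were chosen after the results were seen, as were the GC offset and the omission of both libraries numbered 3 as settings.

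Several of the genes induced from near 0 belong to stratified epithelia, and a list of 56 further genes of squamous differentiation was drawn up after the most induced genes, IVL, SCEL and NCCRP1 among them, had been seen and before the values of the others were. Of these, 14 passed the count filter. ABCA12, which carries lipids to the skin barrier, rose 3.92-fold (13.3 ± 3.88 to 52.1 ± 16.7 CPM, SD, n = 3), MAL 2.97-fold, CDSN 2.67-fold and ALOXE3 2.52-fold, and DSC2 had a log2 fold change of 0.60, a call lost with the GC offset (adjusted p = 0.15). KRT15 fell by 1.27 on the log2 scale, as did EVPL by 0.45, whose call was lost with the GC offset (adjusted p = 0.10). PPL, DSC3 and KRT10 were not called in the main fit but were with the GC offset. There PPL was higher (0.45, adjusted p = 0.0067), and DSC3 and KRT10 were lower (-0.46 and -0.23, adjusted p = 0.015 and 0.033). These genes lie outside the naming rule. The hypothesis that a squamous programme rises as a whole was not borne out: the 14 genes had a median log2 fold change of 0.072 and a camera p of 0.54 (0.55 with an estimated correlation, 0.42 with the GC offset).

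RAET1E and its neighbour RAET1G, ligands of NKG2D, rose 36.4-fold and 10.3-fold (edgeR's quasi-likelihood test, adjusted p = 1.2e-06 and 2.7e-05), and closely related sequence between them may be shared in counting; of this family only RAET1E is within the naming rule. The hypothesis that the other ligands of the family rise with them was not borne out either: edgeR's test called 0 of 5 tested ligands higher (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom and 1 with the GC offset). MICA, MICB and ULBP1 had log2 fold changes of 0.022, 0.13 and 0.066, and ULBP2 and ULBP3 of -0.36 (adjusted p = 0.055) and -0.41 (adjusted p = 0.084). With the GC offset MICA was called (0.20, adjusted p = 0.016) and so was ULBP2 (-0.42, adjusted p = 0.012).

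The number of genes called, 5411, was weighed against grouping by chance and against the GC trend. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many genes, and the highest other gave 1; with 10 splits a share under 0.05 cannot be reached. With the GC offset 89.3% of the called genes that could be tested kept direction and call, which argues against the trend as the source of most calls. It does not say which of the remaining genes are affected, and whether RORγ itself shifts genes by GC content was not tested.

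Ribosomal protein genes were lower in Ad-RORγ by a median of -0.39. The median was -0.297 ± 0.0350 (SE over members) with the GC offset and -0.351 ± 0.0313 without both libraries numbered 3. Both were below the mark of -0.195 set for these tests by more than their errors. Those errors treat member genes as independent and leave out the spread between libraries, so they do not settle either as the whole cause. In these libraries the GC trend as estimated took away only part of the decrease. Leaving out both libraries numbered 3 kept the correlation of fold change with GC content at -0.47. That step therefore does not weigh the GC trend. Only 0.030% of 10000 random lists matched on transcript length and expression had a median as low, but the matching was incomplete: members had a median length of 1155 bases and their neighbours 1538, and the random lists themselves had a median of -0.19. The random lists also treat genes as independent, so the share does not allow for members that move together. With GC and length trends removed together the median was -0.207 ± 0.0381, within its error of that mark, so a joint length and GC trend cannot be told apart from an effect of RORγ for about that part of the decrease. An effect of RORγ on the rest was not tested apart from the group difference itself.

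Of 19 tested clock genes 9 rose and 1 fell, with a median log2 fold change of 0.30 over all 19 and 1.10 over the 9 that rose. Over all 19, camera still called the list higher with the GC offset (adjusted p = 0.0017). This test was chosen once its values were known, so no conclusion about the GC trend is drawn from it. Camera also called the list without both libraries numbered 3 (adjusted p = 0.019), so the call did not rest on those 2 libraries alone. Leaving them out kept the correlation of fold change with GC content at -0.47, so that step does not weigh the GC trend. These calls hold only with camera's preset correlation (with an estimated one, adjusted p = 0.52 in all libraries and 0.44 with the GC offset). The median over all 19, which go both ways, exceeded the mark of 0.15 by less than its error in both settings (0.32 ± 0.21 without the libraries, 0.26 ± 0.22 with the GC offset) and decides nothing. Values over the 9 that rose are not used against either explanation, since the 9 were picked for having risen: their median was 1.05 ± 0.277 without the libraries and 0.68 ± 0.30 with the GC offset, against a mark of 0.55, and 9 of 9 kept direction and call with the GC offset. The GC trend stays open as the whole or a part of the rise, also for single members such as NR1D2 (1.10 to 0.64). The libraries numbered 3 stay open as a part of it, and direct activation by RORγ was not tested.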
